A study of Homo sapiens with 10 samples.

How the data were processed

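The series holds RNA-seq of 10 libraries of sorted GFP-positive A549 cells, in 4 groups: GFP EtOH (n = 3), GFP Dex (n = 3), P300 EtOH (n = 2) and P300 Dex (n = 2). Groups and replicate numbers came from the labels. The labels' protocols name 2 sets of kits, total RNA with a stranded SMARTer kit after E.Z.N.A. extraction and poly(A) RNA with NEBNext Ultra after Quick-RNA extraction, and do not say which was used for which library. Ribosomal RNA genes, nuclear and mitochondrial, held 4.24% and 5.32% of counts in the GFP EtOH and GFP Dex libraries of replicate number 2. The GFP libraries of numbers 1 and 3 held 0.493% to 0.813%. Whether this reflects the kits cannot be told. The deposited table holds raw gene counts, whole numbers per gene and library, per the file headers. Cutadapt, STAR 2.4.2a, HTSeq 0.6.1p1, DESeq2 1.10.1 and GRCh37 are named in the submitters' processing notes. The annotation and the strand setting of the counting are not given in the sources used here, so overlapping, antisense and near-identical genes cannot be told apart by these counts. The other values the authors deposited, a block of 10 columns of normalized counts, were not used. A second deposited file gives the authors' thresholds (adjusted p of 0.05, absolute log2 fold change of 0.58, largest count of 30). Of 25538 genes, none lacked a name, 29 symbols were on more than 1 line, and the smallest maximum over the libraries was 6 counts.

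Totals ran from 2278717 to 13122367 counts. Shares of counts have 95% Clopper-Pearson intervals and zeros a floor of 3 counts over the group. Both cover counting error only, since reads without molecular identifiers are not independent molecules. A chi-square test over the 8 pairs of libraries within a group found none that differed by as little as sampling noise, and pairs across groups were not tested.

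The main test, fixed before the data were examined, was edgeR 4.0.16's quasi-likelihood test in R 4.3.3 on all 10 libraries (TMM factors, default expression filter by group, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05, for 5 contrasts: Dex in GFP, Dex in P300, P300 in EtOH, P300 in Dex and their interaction. Of the genes, 19433 passed the filter. All tests are two-sided except Fisher's exact tests of symbol groups, which are one-sided. CPM use the TMM-scaled library sizes and log2 CPM a prior count of 2. Gene lists (25 fixed before the data were examined, 24 with at least 5 tested genes) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists of a contrast. List medians are of log2 CPM differences and are given minus the median of all genes on that scale, which was 0.00 for Dex in GFP, 0.27 for Dex in P300, -0.40 for P300 in EtOH, -0.13 for P300 in Dex and 0.27 for the interaction, while counts of members above or below 0 are not shifted. Named genes followed a rule fixed before the data were examined: per contrast the 10 largest rises and falls among called genes of at least 1 CPM whose groups did not overlap, otherwise the 5 smallest p, plus up to 4 members per list and EP300, CREBBP and NR3C1. Genes named from the blocked fits by size were added after seeing the data, and the names given are a selection, from which 1 gene is not reported here. GC content came from GENCODE 29 by gene identifier for 18863 of the 19433 genes (97.1%).

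Replicate numbers appeared to pair the samples. Deviations from the group means correlated between all 13 pairs of libraries with the same number (r = 0.113 to 0.601) and at -0.484 to 0.240 between 24 pairs of different numbers. Deviations cancel within a group and mirror each other in the groups of 2, so these values are not independent of each other. Between the GFP groups of 3, r was 0.357, 0.601 and 0.412 for the same number and -0.484 to 0.202 for different numbers. Values with the number as a block are therefore given where they change a call. Alternatives fixed before the data were examined were the block, DESeq2 1.42.0, limma-voom, RLE factors or none, a stricter filter (5 CPM in 2 libraries) or none, a log2 fold of at least 1, only the libraries compared, GFP libraries limited to the numbers P300 has, mitochondrial and ribosomal RNA genes removed, and each library left out. Alternatives chosen after seeing the data were the block within the libraries compared, GC correction, EP300 removed, voom with quality weights, robust estimation, the authors' thresholds and thinning.

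The steps were tested on simulated data, with the settings extended after a first simulation had shown false calls, 5 draws each, with 200 changed genes per draw (2-fold and 4-fold, 100 each) and with means and spreads taken from the libraries. With a spread shared by all libraries, the fit of 10 made 9 false calls of 249 for Dex in GFP, 0 of 47 for Dex in P300, 4 of 104 for P300 in EtOH and 2 of 142 for P300 in Dex. With separate spreads for GFP and P300 libraries, it made 0 of 98, 2834 of 3117, 50 of 142 and 114 of 244, so its adjusted p did not hold its nominal rate where P300 libraries were compared. It then recovered 0% of 2-fold and 19.6% of 4-fold changes for Dex in GFP (about 17771 genes tested) and 0.8% and 17.6% for P300 in EtOH (17807 genes). The 6 GFP libraries with block, simulated with the number effects and the spread left after the block, recovered 98.4% and 100% with 61 false calls of 1053 (16686 genes). Those counts followed the model that the blocked fit assumes, with the same number effect in EtOH and Dex and genes drawn independently. The real libraries of number 2 differed in GC trend, with bin medians of -0.29 to 0.40 in GFP EtOH and 0.04 to 0.09 in GFP Dex. The simulation therefore does not show how the blocked fit behaves on the real libraries. DESeq2 with separate spreads made 11 false calls of 427 for Dex in GFP and 2768 of 3207 for P300 in EtOH. Voom with quality weights made 102 of 816 for Dex in GFP and 0 of 52 for P300 in EtOH. The main design was kept as fixed, and these rates stand beside its counts. A planted list was the 1 list called of 23, in 1 draw. Genes were drawn independently there, so this does not show how camera with the preset correlation behaves where genes are correlated.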

Results

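RNA was sequenced from A549 cells, a human lung adenocarcinoma line, that had been transfected with a vector for GFP or for a fusion of EP300 with GFP. EP300 (p300) is a histone acetyltransferase and coactivator. At 48 h after transfection with 1 ug of vector, the cells received ethanol (EtOH) or 100 nM dexamethasone (Dex), a synthetic glucocorticoid, for 1 h, and GFP-positive cells were sorted. There were 3 GFP EtOH, 3 GFP Dex, 2 P300 EtOH and 2 P300 Dex libraries. Of the 10 libraries, 9 held 9215550 to 13122367 gene counts. The P300 EtOH library of replicate 2 held 2278717 counts and had 11861 of 25538 genes at 0, and at its depth 3 counts correspond to 1.32 CPM (counts per 1e+06 counts). Depth alone does not account for its zeros. With each library thinned to about 1.8e+06 counts without EP300, it had counts for 13661 genes, against 18745 to 20444 in the other 9. The libraries of a group correlated at r = 0.965 to 0.985 across genes in the GFP groups, at 0.766 in P300 EtOH and at 0.836 in P300 Dex, and genes are not independent replicates. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

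EP300, the transfected gene, was checked first. It took 0.0271% to 0.0386% of the counts in the GFP libraries. In the P300 libraries it took 28.6% (95% Clopper-Pearson interval 28.5% to 28.6%) in EtOH replicate 1, 28.8% (28.8% to 28.8%) in Dex replicate 1, 13.4% (13.4% to 13.5%) in EtOH replicate 2 and 2.42% (2.41% to 2.43%) in Dex replicate 2. The mean EP300 level was 9.55 ± 0.98 (SE) higher on the log2 scale in P300 than in GFP cells in EtOH (edgeR adjusted p = 0.00516) and 9.22 ± 0.97 higher in Dex (adjusted p = 0.00974). The counts do not separate transcripts of the vector from those of the cell's own gene. CREBBP, the paralog of EP300, and NR3C1, the glucocorticoid receptor, did not pass the test in any of the 5 comparisons.

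**Figure D1:**
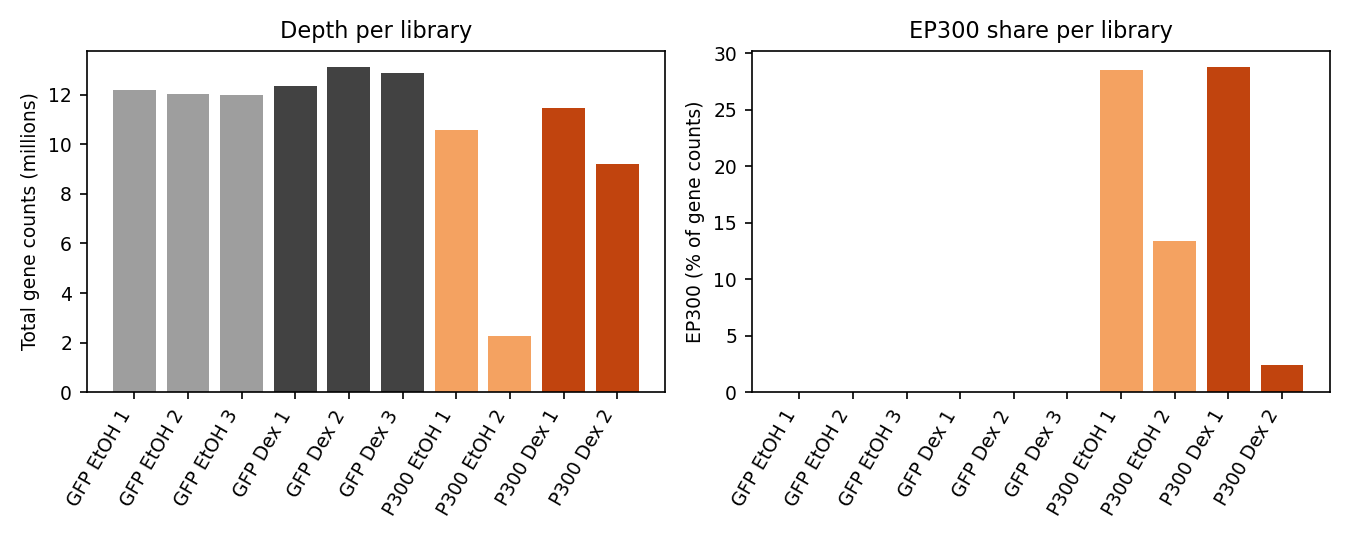
Total gene counts (left, in units of 1e+06 counts) and the percentage of gene counts assigned to EP300 (right) for each of the 10 libraries, 1 bar per library. EP300 held 28.6%, 13.4%, 28.8% and 2.42% of the counts in the 4 P300 libraries, and the P300 EtOH library of replicate 2 was the shallowest at 2278717 counts.

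The first comparison asked which genes 1 h of Dex changed in GFP cells. Known targets induced by the glucocorticoid receptor were higher as a group: 45 of 47 had a positive log2 fold change, with a median 0.86 above that of all genes. Immediate early genes were lower as a group, with 19 of 23 below 0 and a median of -0.45 relative to all genes (camera adjusted p = 0.11 with an estimated correlation, and fry adjusted p = 0.604). Not shifted by all genes, their median was -0.15, -0.80 and -0.48 in the GFP pairs of number 1, 2 and 3. Single genes did not pass the planned test. edgeR on all 10 libraries called 0 of 19433 genes, with 113 at an unadjusted p under 0.05. ERRFI1, a feedback inhibitor of EGF receptor signalling, had the smallest p and a log2 fold change of 1.28 ± 0.23 (SE), from 138 ± 12.3 to 333 ± 19.7 CPM (SD, n = 3 each). DESeq2 called 5 genes (4 higher, 1 lower), limma-voom 0, edgeR with the replicate number as a block in the fit of 10 0, voom with library quality weights 89 (67 and 22) and edgeR on the 6 GFP libraries alone 7 (all higher). The same 6 libraries with the replicate number as a block gave 277 of 16697 genes (171 rose, 106 fell). Without replicate number 1, 2 or 3 that fit gave 363, 1198 and 248 genes. This blocked GFP fit combined planned choices only after the data had been seen. Over the 35 fits run for this comparison 9 gave any call, and 7 of those 9 were chosen after seeing the data.

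In the blocked GFP fit, TSC22D3 (GILZ), an anti-inflammatory glucocorticoid target, rose by 2.56 ± 0.26 (log2, SE; edgeR adjusted p = 2.4e-04), from 32.7 ± 27.9 to 161 ± 20.3 CPM (SD, n = 3 each). TFCP2L1, a transcription factor gene, rose by 2.25 ± 0.14, the thiamine transporter gene SLC19A2 by 1.79 ± 0.14, the circadian repressor gene PER1 by 1.63 ± 0.16 and NFKBIA, an inhibitor of NF-kappaB, by 0.95 ± 0.09. EGR3, an immediate early transcription factor, fell by 2.22 ± 0.38, the chemokine gene CXCL3 by 1.39 ± 0.15, IER2 by 0.95 ± 0.15 and JUN by 0.69 ± 0.09. Of the glucocorticoid-induced list, 32 of 46 members rose (39 adjusted over the list alone) and 0 fell. In the planned fit 0 members passed (15 adjusted over the list alone). Of the glucocorticoid-repressed list 11 of 43 fell in the blocked fit and 0 rose (17 and 1 adjusted over the list alone), among them CXCL3 and the feedback gene IER3 at -0.86 ± 0.12. Of the immediate early list 12 of 23 fell (15 adjusted over the list alone). For both lists, 0 members passed in the planned fit and 0 adjusted over the list alone.

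Camera with a preset correlation called 6 of 24 lists for Dex in GFP cells. The glucocorticoid-induced list had an adjusted p = 1.8e-49 and, with an estimated correlation, an adjusted p = 0.0175, which rose to an adjusted p = 0.517 with an estimated correlation in the blocked GFP fit. The immediate early list had an adjusted p = 4.0e-10 (adjusted p = 0.11 with an estimated correlation) and the glucocorticoid-repressed list an adjusted p = 1.1e-06 (adjusted p = 0.60 with an estimated correlation). Genes of the G2 and M phases were higher in 27 of 28 cases, with a median 0.21 above all genes (adjusted p = 1.2e-04, and adjusted p = 0.72 with an estimated correlation). S phase genes had a median 0.15 above all genes (adjusted p = 0.0055, and adjusted p = 0.79 with an estimated correlation) and heat shock genes 0.22 (adjusted p = 0.023, and adjusted p = 0.79 with an estimated correlation). In the blocked fit 1, 0 and 0 members of these 3 lists passed (8, 2 and 0 adjusted over the list alone). Fry called 0 lists. Without GFP EtOH replicate 1 the G2 and M list had an adjusted p = 0.14 and the S list 0.208, and without GFP Dex replicate 3 they had 0.255 and 0.265. Their medians ran from 0.10 and 0.08 without GFP Dex replicate 3 to 0.35 without GFP EtOH replicate 3 and 0.24 without GFP Dex replicate 1. The heat shock list was lost without GFP Dex replicate 1 (adjusted p = 0.12), GFP EtOH replicate 2 (0.72), P300 Dex replicate 2 (0.053) or GFP Dex replicate 3 (0.35), and its median turned to -0.05 without GFP EtOH replicate 2 and was 0.02 without GFP Dex replicate 3. The glucocorticoid-repressed median was -0.35 without GFP Dex replicate 1 and -0.11 without GFP Dex replicate 2, and the immediate early median -0.30 without GFP EtOH replicate 2.

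**Figure D2:**
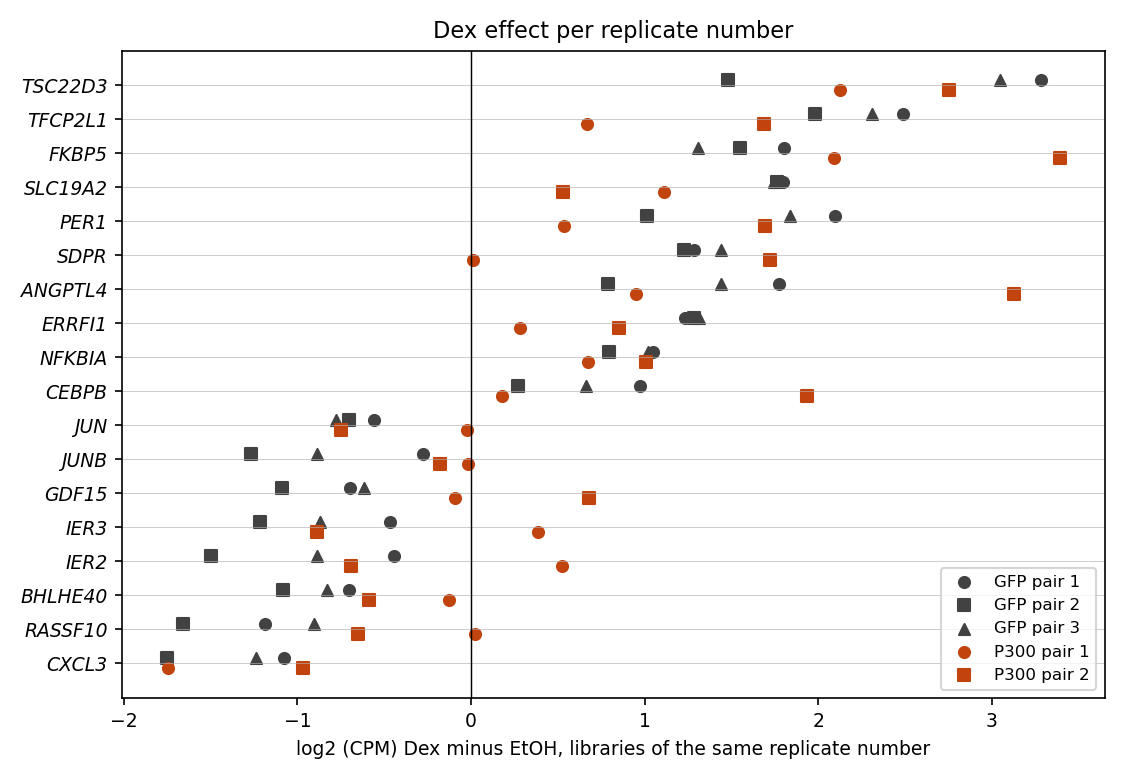
Log2 CPM in Dex minus EtOH for 18 genes, with 1 point per pair of libraries of the same replicate number, in GFP cells (dark, 3 pairs) and P300 cells (orange, 2 pairs). For TSC22D3 the GFP pairs lay at 3.28, 1.48 and 3.05 and the P300 pairs at 2.13 and 2.75.

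The second comparison asked the same of P300 cells. Glucocorticoid-induced genes were again higher as a group, with 43 of 47 positive and a median 0.60 above all genes (camera adjusted p = 0.028, and adjusted p = 0.97 with an estimated correlation). The 15 mitochondrially encoded genes had a median of -0.67 relative to all genes, 14 of them below 0 (adjusted p = 0.0022, and adjusted p = 0.97 with an estimated correlation). FKBP5, a chaperone and feedback regulator of the receptor, had a log2 fold change of 3.08 ± 0.60 (SE), from 9.75 ± 3.28 to 80.4 ± 68.2 CPM (SD, n = 2 each; edgeR adjusted p = 0.139). Single genes did not pass: edgeR called 0 of 19433, with 2569 at an unadjusted p under 0.05, limma-voom and voom with quality weights 0 each, and DESeq2 503 (353 higher, 150 lower). The 4 P300 libraries alone with the replicate number as a block, chosen after seeing the data, gave 6 genes, all higher. They included FKBP5 (2.72 ± 0.55), PDK4, a regulator of pyruvate oxidation (2.22 ± 0.41), and the transcription factor gene CEBPD (2.21 ± 0.44). Over all fits run, FKBP5 ranged from 1.76 to 3.80, PDK4 from 1.06 to 3.59 and CEBPD from 0.59 to 3.92. Of the glucocorticoid-induced list 4 of 47 rose in that fit (10 adjusted over the list alone), and in the planned fit 0 passed (1 adjusted over the list alone). The median of all genes was itself shifted by 0.27 on the scale of the list medians and by 0.13 in edgeR's fit.

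The calls of this second comparison depended on single libraries. Without P300 EtOH replicate 1 edgeR called 2394 genes, of which 1285 of the 1818 higher ones (70.7%, against 36.6% of all genes tested) were at 0 in the shallow library left as the only EtOH library, and without P300 Dex replicate 1 it called 203. In counts simulated with the spread of each construct, 9999 of 10503 DESeq2 calls for this comparison were at unchanged genes. The glucocorticoid-induced list was lost without P300 EtOH replicate 1 (adjusted p = 0.44), P300 EtOH replicate 2 (0.13) or P300 Dex replicate 2 (0.51). The glucocorticoid-repressed list (median -0.35 relative to all genes and -0.08 by itself, adjusted p = 0.317) passed without P300 Dex replicate 1 (-0.88, adjusted p = 0.0060) and turned to 0.18 without P300 Dex replicate 2, and the mitochondrial list was lost when P300 Dex replicate 1 (0.085) or P300 EtOH replicate 2 (0.61) was left out. Its median was -0.34 without P300 EtOH replicate 2 and -1.04 without P300 EtOH replicate 1, and the glucocorticoid-induced median was 0.34 without P300 EtOH replicate 1, 0.26 without P300 Dex replicate 2 and 0.93 without P300 Dex replicate 1.

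The third comparison tested whether the Dex effect itself differed between P300 and GFP cells. edgeR called 0 of 19433 genes for the interaction, with 1697 at an unadjusted p under 0.05. Limma-voom and voom with quality weights called 0 and DESeq2 128 (99 higher, 29 lower). The glucocorticoid-induced list had a median interaction of -0.39 relative to all genes (camera adjusted p = 0.198) and the glucocorticoid-repressed list -0.08 (adjusted p = 1.0). Not shifted by all genes, whose median was 0.27 on this scale, the medians were -0.12 (23 of 47 positive) and 0.19 (34 of 45 positive). Relative to all genes, the repressed list ran from -0.46 without P300 Dex replicate 1 to 0.47 without P300 Dex replicate 2. The median Dex effect of the induced list was 1.14, 0.65 and 1.02 in the GFP pairs and 0.34 and 1.35 in the P300 pairs. FKBP5 moved by 1.80, 1.55 and 1.31 in the GFP pairs and by 2.09 and 3.39 in the P300 pairs, while KLF9, another receptor target, moved by 2.26, 1.44 and 1.70 against -0.73 and 1.05. Their interaction terms were 1.53 ± 0.72 (SE, edgeR adjusted p = 0.598) and -1.93 ± 0.86 (adjusted p = 0.558).

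The mitochondrially encoded genes were the 1 list called for the interaction, with a median of -0.535 relative to all genes and 14 of 15 below 0 (camera adjusted p = 0.0201, and adjusted p = 1.0 with an estimated correlation), and the call was lost without any of GFP EtOH replicate 1 (0.057), P300 EtOH replicate 1 (0.069), P300 Dex replicate 1 (0.27), GFP Dex replicate 2 (0.34), P300 EtOH replicate 2 (0.87) and GFP EtOH replicate 3 (0.22). The glucocorticoid-induced list passed without GFP EtOH replicate 2 (-0.49, adjusted p = 0.0047) or P300 Dex replicate 2 (-0.76, adjusted p = 0.0062). Without P300 EtOH replicate 1, 1407 genes were called for the interaction. As a check with the measured GFP pair left out of the picking, the 100 genes with the smallest p for a rise in 2 GFP pairs had a mean of the median log2 fold of 0.88 in the left-out GFP pairs, 0.35 in P300 pair 1 and 0.98 in P300 pair 2. The P300 libraries were part of the picking fits, where they shared in the expression filter and the estimate of spread. The 100 genes picked for a fall gave -0.51, -0.04 and -0.52. In the reverse check, genes picked for Dex in P300 cells and measured in GFP gave -0.011 for a rise and 0.0085 for a fall. Those picks came from the fit of all libraries, the GFP libraries included. In counts simulated with separate spreads, 2834 of 3117 calls of that fit for Dex in P300 cells were at unchanged genes. Many of the picks may thus be library noise, so values near 0 do not show that genes responding in P300 cells fail to respond in GFP cells. The median of all genes was 0.04 in P300 pair 1 and 0.48 in P300 pair 2. The picking by adjusted p that had been fixed first found 0 genes in each of the 3 picks, so the smallest p were used in its place.

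The fourth comparison set P300 against GFP cells in EtOH. Of the 310 genes higher in P300 cells, 140 were under 1 CPM in GFP cells, where 3743 of the 19433 genes tested lay. COL6A3, a chain of type VI collagen, was at 0.493 ± 0.170 CPM (SD, n = 3) in GFP and 85.5 ± 11.9 CPM (SD, n = 2) in P300 cells, a rise of 7.41 ± 0.63 (log2, SE; edgeR adjusted p = 0.00227). XIRP1, an actin-binding protein of striated muscle, rose by 7.76 ± 0.93 and the neurofilament gene NEFM by 5.99 ± 0.95. CRX, a photoreceptor transcription factor, had 0 counts in the 3 GFP libraries and was at least 86.2-fold higher in P300 cells, against a floor of 3 counts over the group. Among genes expressed in both, the deacetylase gene HDAC5 rose by 2.28 ± 0.42. Genes that fell included IFI44L, an interferon-induced gene (-1.78 ± 0.31), NFKB2, a subunit of NF-kappaB (-1.47 ± 0.31), and DDB2, a p53 target in DNA repair (-1.80 ± 0.38). TPX2, a spindle assembly factor, fell by 1.73 ± 0.41 (adjusted p = 0.0479), with an adjusted p = 0.0600 when the replicate number was a block.

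edgeR called 541 of 19433 genes in this comparison, 310 higher and 231 lower, with 5042 at an unadjusted p under 0.05. The median of all genes was shifted by -0.18 with TMM factors, by -0.04 with RLE factors and by -0.41 with library sizes alone, and the split was 355 higher and 191 lower with RLE factors and 301 and 414 with library sizes alone. Other fits differed in how many lower genes they called. Voom with quality weights called 455 higher and 2 lower genes, which included 268 of the 310 higher and 1 of the 231 lower genes, and edgeR on the 5 libraries compared called 49 higher (48 of the 310) and 0 lower. With the replicate number as a block, those 5 libraries gave 248 higher and 345 lower genes, 156 of them among the 541, and the 10 libraries gave 266 and 230, 323 of them among the 541. DESeq2 gave 1368 higher and 1072 lower genes. Of the 310 higher genes, 299 (96.5%) also had a positive log2 fold change in Dex, in other libraries, against 49.9% of all genes. These sets are not matched for level, since 45.2% of the higher genes and 19.3% of all genes were under 1 CPM in GFP EtOH. Genes that low can pass the expression filter through the P300 libraries, which favours positive signs. Tested genes under 1 CPM in GFP EtOH summed to 3.71 and 1.52 times the GFP Dex level in P300 Dex replicates 1 and 2. Of the 231 lower genes, 67 were positive in Dex. In the shallow P300 EtOH library of replicate 2, 168 of them were at 0, against 6110 of all 19433 genes tested. In both P300 EtOH libraries 109 of them were at 0, against 1255 of all genes tested. Libraries of the same number deviated together, so EtOH and Dex libraries are not fully independent.

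The 541 calls rest on a spread shared by all 10 libraries, although the common dispersion was 0.0596 in the GFP and 0.596 in the P300 libraries. In counts simulated with those separate spreads, 50 of 142 calls for this comparison (35.2%) were at unchanged genes, against 4 of 104 with a shared spread. Voom with quality weights made 0 such calls among 52 and edgeR on the 5 libraries compared 0 among 1. Leaving out a GFP library ended nearly all calls: 0, 2 and 1 remained without GFP EtOH replicate 1, 2 and 3, and 4, 3 and 5 without GFP Dex replicate 1, 2 and 3. Without P300 EtOH replicate 1 and 2 there were 4187 and 1073, and without P300 Dex replicate 1 and 2 there were 2218 and 2162.

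Interferon response genes were lower as a group in P300 cells in EtOH, with 41 of 41 below 0 and a median of -0.68 relative to all genes (camera adjusted p = 9.2e-05, and adjusted p = 0.58 with an estimated correlation). Of these, 2 fell and 0 rose (12 and 0 adjusted over the list alone), and with the replicate number as a block in the 5 libraries compared 25 fell (32 adjusted over the list alone). G2 and M phase genes were lower in 28 of 28 cases, with a median of -0.83 relative to all genes (adjusted p = 1.2e-04, and adjusted p = 0.58 with an estimated correlation), and 1 fell (12 adjusted over the list alone), against 7 (17) with that block. S phase genes had a median of -0.43 (adjusted p = 0.020, and adjusted p = 0.69 with an estimated correlation), and 0 passed (2 adjusted over the list alone), against 2 (7) with that block. Mitochondrially encoded genes were higher, with 14 of 15 positive and a median of 0.93 (adjusted p = 1.8e-04, and adjusted p = 0.58 with an estimated correlation), and MT-ATP6 rose by 1.00 ± 0.22 (1 adjusted over the list alone, and 2 rose with that block, or 7 adjusted over the list alone). Endothelial and erythroid markers, which GFP cells held at a median of 0.407 CPM, were positive in 7 of 7 cases (adjusted p = 0.0019, and adjusted p = 0.24 with an estimated correlation), and 2 rose (4 adjusted over the list alone). These 2, TIE1 and VWF, lost the call with the block in the fit of 10 (adjusted p = 0.110 and 0.0845), and 0 of 5 members passed with the block in the 5 libraries. TIE1 and VWF lay at 1.33 and 2.44 CPM in P300 EtOH replicate 1 and at 13.9 and 9.39 CPM in the shallow replicate 2. Of the 15 markers 7 were tested, and 2 of these reached 1 CPM in GFP cells. The expression filter thus admitted others partly through the P300 libraries, which favours positive signs. With the block in the 5 libraries, 4 of 5 were positive. Fry called 4 lists at an adjusted p of 0.0291: interferon, G2 and M, endothelial, and endoplasmic reticulum (ER) stress genes. It tests whether members move 1 way on balance from 0 and not relative to all genes, whose median was -0.40. Its calls of lower lists can therefore reflect that shift. Camera with the preset correlation and no block gave the ER stress list an adjusted p of 0.122. With the replicate number as a block, camera also called lower ER stress genes (adjusted p = 0.025), lower core histone genes (0.025) and higher ribosomal protein genes (0.035). With an estimated correlation and no block these 3 lists had an adjusted p of 0.693, 0.720 and 0.720. The S phase median was -0.27 without P300 EtOH replicate 1, and its call was lost with the block and GC correction (adjusted p = 0.065). The interferon median was -1.06 without P300 EtOH replicate 2, and the list was lost without P300 EtOH replicate 1 (median -0.27, adjusted p = 0.104) and the mitochondrial list without P300 EtOH replicate 2 (0.085). Of the glucocorticoid-induced list, 1 member rose and 0 fell (4 and 2 adjusted over the list alone), while with the block in the 5 libraries 0 rose and 7 fell (0 and 8 adjusted over the list alone), and the list passed camera only without GFP EtOH replicate 2 (adjusted p = 0.035).

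**Figure D3:**
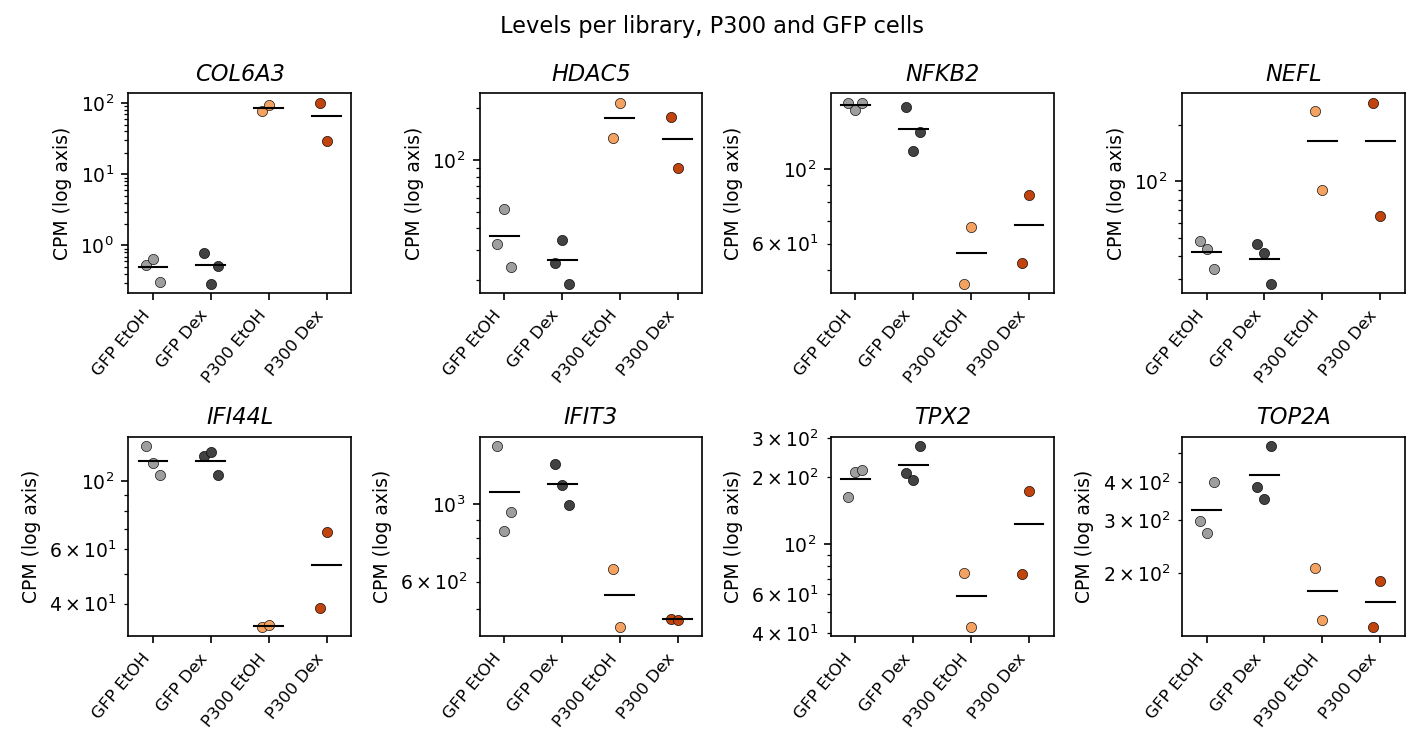
CPM on a log axis for 8 genes in each of the 10 libraries, with 1 point per library and a line at the group mean. COL6A3 averaged 0.493 CPM in GFP and 85.5 CPM in P300 cells in EtOH, and IFI44L lay lower in all 4 P300 libraries than in the 6 GFP libraries.

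The fifth comparison set P300 against GFP cells in Dex. COL6A3 rose by 6.94 ± 0.62 (log2, SE; edgeR adjusted p = 0.00363), from 0.527 ± 0.244 CPM (SD, n = 3) to 65.5 ± 51.2 CPM (SD, n = 2), and with EP300 it made up the 2 genes called, both higher. SLC17A7, a vesicular glutamate transporter gene, had a log2 fold change of 5.69 ± 0.75 (adjusted p = 0.0597) and HDAC5 2.35 ± 0.42 (adjusted p = 0.0812). G2 and M phase genes were lower in 28 of 28 cases, with a median of -0.94 relative to all genes (camera adjusted p = 1.9e-10, and adjusted p = 0.45 with an estimated correlation). Interferon response genes were lower in 35 of 41 cases, with a median of -0.70 (adjusted p = 9.5e-09, and adjusted p = 0.45 with an estimated correlation). Of these 2 lists, 0 members passed (7 and 6 lower ones adjusted over the list alone). TOP2A, a topoisomerase of dividing cells, had a log2 fold change of -1.40 ± 0.32 and IFIT3, an interferon-induced gene, -1.29 ± 0.31. S phase genes (median -0.41, adjusted p = 0.0042, and adjusted p = 0.62 with an estimated correlation) were lower, with 0 members passing and 0 adjusted over the list alone. Fibroblast markers (1.17, adjusted p = 0.0079, and adjusted p = 0.54 with an estimated correlation; 1 member, COL6A3, and 3 adjusted over the list alone) and endothelial and erythroid markers (7 of 7 positive, adjusted p = 0.0047, and adjusted p = 0.32 with an estimated correlation; 0 members and 4 adjusted over the list alone) were higher. In GFP cells 6 of 13 tested fibroblast and 2 of 7 tested endothelial and erythroid markers reached 1 CPM. The expression filter thus admitted others partly through the P300 libraries, which favours positive signs. With the replicate number as a block in the 5 libraries compared, 5 of 8 and 4 of 4 were positive, and the fibroblast median was 0.44.

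edgeR gave the 2 calls among 19433 genes in Dex, with 2463 at an unadjusted p under 0.05. DESeq2 gave 712 (584 higher, 128 lower), limma-voom 1, voom with quality weights 47 (all higher) and edgeR on the 5 libraries compared 0. Those 5 libraries with the replicate number as a block, chosen after seeing the data, gave 150 (139 rose, 11 fell), among which the interferon-induced genes IFIT2 (-1.75 ± 0.40) and RSAD2 (-1.70 ± 0.43) fell. With that block in the fit of 10, camera also called lower NF-kappaB and cytokine genes (adjusted p = 0.016) and lower ER stress genes (0.021), each with an adjusted p = 0.618 with an estimated correlation and no block. Fold changes followed GC content here, with Spearman's rho of 0.52 across genes, and -0.56 for Dex in GFP cells. In simulated counts with separate spreads 114 of 244 edgeR calls and 3835 of 4312 DESeq2 calls for this comparison were at unchanged genes. Without P300 Dex replicate 2 there were 499 calls, without GFP Dex replicate 1 there was 1, and without GFP Dex replicate 2 or 3 there were 0. The interferon, S phase, fibroblast and endothelial lists were lost without P300 Dex replicate 1 (adjusted p = 0.15, 0.57, 0.22 and 0.20). Without it the interferon median was -0.15 and the S phase median -0.21, and the fibroblast median turned to -0.14. Without P300 Dex replicate 2 these 3 medians were -1.32, -0.82 and 2.06.

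In the fit without the block, the other lists passed camera with the preset correlation in none of the 5 comparisons. They held targets of p53, hypoxia, clock, cholesterol synthesis, TGF-beta and YAP genes, acetyltransferases and deacetylases, core histones, ribosomal proteins, nuclear noncoding RNA, ER stress, NF-kappaB and cytokines, and markers of lung epithelium, leukocytes and neural or HEK cells. The smallest adjusted p among lists not called was 0.0913 for Dex in GFP cells, 0.312 for Dex in P300 cells, 0.0793 for P300 in EtOH, 0.114 for P300 in Dex and 0.198 for the interaction. Metallothioneins had 4 members tested, under the minimum of 5.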

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

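Chosen only after the result was seen were the tests of fibroblasts, of the EP300 level, of an effect in both treatments, of GC content for the blocked calls and of the P300 spread, and all fits with the block in the compared libraries alone or with GC correction.

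The Dex effects of 3 genes pointed 1 way in all 3 GFP pairs and the other way in both P300 pairs, and that rule is not a test. They were LIF, a cytokine (P300 mean minus GFP mean of 1.12, log2), LINC00926, a noncoding RNA (4.87), and SALL4, a transcription factor (5.32). edgeR's test of the interaction gave them an adjusted p of 0.442, 0.308 and 0.308. Among genes named for Dex 3 of 51 (5.88%) showed it, against 1679 of 19433 tested (8.64%), and the share that chance gives was not computed. LINC00926 and SALL4 had been named for their small p for Dex in P300 cells and the interaction in these same libraries, so their flag adds no support. Over all fits run, their interaction terms ran from 4.81 to 9.41 and from 5.15 to 10.0, so their size is uncertain. The mitochondrially encoded genes stood out by camera on the interaction, with a median of -0.535 relative to all genes (adjusted p = 0.0201, and adjusted p = 1.0 with an estimated correlation). Leaving out single libraries gave -0.25 (without P300 EtOH replicate 2) to -0.94 (without P300 EtOH replicate 1), and the call was lost with GC correction (0.157), with the block and GC correction (0.0571), with EP300 removed (0.0752) and with thinning (0.0555).

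For the first pattern, genes higher in P300 cells in EtOH, GC content predicted a median log2 fold change in the Dex libraries of 0.25 or less after correction. With the block and GC correction it was 2.44. The correction could hardly have lowered 2.53 that far, since medians for P300 in Dex ran only from -0.44 to 0.26 over bins of GC content. That trend is too small for the rise, but it was fitted on 9653 better expressed genes. Of the 310 higher genes 140 lay under 1 CPM in GFP cells, so GC content stays undecided for genes of low expression. Fibroblasts among the sorted cells were argued against as the source of COL6A3, since COL1A2 plus COL3A1 reached at most 0.0489 of its CPM in the 4 P300 libraries, and the sort for GFP removes untransfected cells. COL1A1 was higher in each P300 library (39.9 to 72.4 CPM) than in any GFP library, which by itself goes with that explanation. The rise in Dex was larger by 1.55 (log2) in the pair with more EP300, but in EtOH it was 3.03 in pair 1 with more EP300 and 3.34 in pair 2, and each pair is 1 library per construct and also differs in replicate number, so the EP300 level and the number cannot be told apart. An effect of P300 on these genes and library differences tied to the construct both stay open and were not tested.

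Genes lower in P300 cells in EtOH were the second pattern. Of 1922 genes at 5 to 10 CPM in GFP EtOH, 13 were at 0 in both P300 EtOH libraries against 5.21 from the product of their shares, a ratio of 2.50 (exact Poisson interval 1.33 to 4.27). The bound of over 2 set beforehand against random loss was passed by the ratio but not by its interval, whose use was added after the value was seen, and unequal levels among these genes also raise the ratio. The median log2 fold change of the 231 genes in Dex was -0.35, and it was -0.16 with GC correction and -0.20 with the block and GC correction, between the values predicted with (-1) and without (-0.1) an effect in both treatments. Random loss from libraries that sampled few molecules and an effect of P300 cannot be told apart here.

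For the third pattern, the 277 Dex calls of the blocked GFP fit against 0 in the fit of 10, GC content as the whole explanation was argued against, since 266 of the 277 genes were called again with GC correction. The spread of the P300 libraries stays open as the reason for the 0, since the 6 GFP libraries without the block called 7 and the block in the fit of 10 called 0. A bound first set against it was replaced after the value was seen, because any call without the P300 libraries goes with it. In counts simulated with separate spreads, the 6 GFP libraries without the block recovered 37.4% of 2-fold and 98% of 4-fold changes. The fit of 10 recovered 0% and 19.6% there. The P300 spread can thus lower the number of calls, but its share in the 0 here was not tested. The 10 splits of the 6 GFP libraries are too few for a share under 0.05: the real split gave 277 with the block and 7 without it, where it was the 1 split with as many and the highest other gave 0, and in the fit of 10 all 10 splits gave 0. Of the other splits with the block, those that part all 3 pairs, as the real one does, also gave 0.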

How the results depend on the processing

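Chosen after seeing the data were the block in the compared libraries, GC correction, quality weights, robust estimation, EP300 removal, the authors' thresholds, thinning, the numbers left out of the blocked GFP fit and the sizes of 50 and 200 picked genes. Of 34 called values of named genes, all kept their direction under all alternatives run (936 values), and 346 of these lost the call. Many of these genes were picked for large changes without overlap between groups, and the alternatives refit the same libraries. Their kept directions were therefore largely fixed by the picking and are no independent support. Of 109 values not called, 32 of 3131 changed direction and 379 passed. Of 19 called list results, 319 of 321 values kept their direction and 65 lost the call. The 2 that turned were heat shock for Dex in GFP without GFP EtOH replicate 2 (-0.048, range over libraries left out -0.048 to 0.349) and fibroblast markers for P300 in Dex without P300 Dex replicate 1 (-0.14, range -0.14 to 2.06). Of 7 list results not called, 12 of 119 values changed direction and 4 passed. Except where a value or the number of libraries shows it, the cause was not tested.

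DESeq2 gave 5 genes for Dex in GFP, 503 for Dex in P300, 2440 for P300 in EtOH, 712 for P300 in Dex and 128 for the interaction. Limma-voom gave 354 for P300 in EtOH and 1 in Dex, and quality weights gave 89 for Dex in GFP and 47 for P300 in Dex. With only the libraries compared there were 7 for Dex in GFP, 49 for P300 in EtOH and 0 in Dex. With the replicate block added to them there were 277 for Dex in GFP, 6 for Dex in P300, 593 for P300 in EtOH (248 higher, 345 lower) and 150 for P300 in Dex, and with the block and GC correction 402, 6, 541 (350 and 191) and 199. The blocked GFP fit gave 363, 1198 and 248 without number 1, 2 and 3, and the GFP libraries with GC correction and no block 2. Without the GFP libraries of number 3, P300 in EtOH and in Dex gave 0. GC correction gave 1054 for P300 in EtOH, thinning 99 there and 1 in Dex, EP300 removal 1 in Dex and no low-count filter 14 in Dex.

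Leaving out 1 library at a time gave 0 for Dex in GFP, 0 to 2394 for Dex in P300, 0 to 4187 for P300 in EtOH, 0 to 499 for P300 in Dex and 0 to 1407 for the interaction, with the upper end without P300 EtOH replicate 1, or P300 Dex replicate 2 for P300 in Dex. A group left with 1 library was assumed to vary like the others. The interaction of the glucocorticoid-induced list ran from -0.76 without P300 Dex replicate 2 to -0.012 without P300 Dex replicate 1.

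For genes picked as raised by Dex, 50 genes gave 1.16 in the left-out GFP pairs, and 200 genes gave 0.66 there, 0.20 in P300 pair 1 and 0.82 in P300 pair 2. Picked in P300 and measured in GFP, the raised genes gave -0.011. For lowered genes, 50 gave -0.65 in GFP, 200 gave -0.43 in GFP, 0.022 in P300 pair 1 and -0.31 in P300 pair 2, and those picked in P300 gave 0.0085 in GFP. The picks in P300 came from a fit whose simulated calls for that comparison were mostly at unchanged genes, so their GFP values decide nothing.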

Other observations

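The test of genes near silence and its gene set were chosen after the data were seen, since 140 of the 310 genes higher in P300 EtOH (45.2%) were under 1 CPM in GFP cells and a first set had been drawn from the genes tested, which the expression filter admits partly through the P300 libraries.

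With no expression filter, the summed CPM of genes at 0.5 to 1 CPM in the GFP libraries of the other treatment was 2.18 and 2.03 times that of the GFP libraries in P300 EtOH, 2.16 and 1.249 times in P300 Dex, and 0.882 to 1.20 times in the 6 GFP libraries. The hypothesis that P300 cells hold more RNA of such genes was left open: it called for over 1.5 times in each P300 library, and the lowest value, 1.249, just met the bound set against it, by less than the SD of 0.135 between GFP libraries, a spread applied after the value was seen. A background spread evenly over silent genes, such as genomic DNA, was not excluded either: the 1% of tested genes under 1 CPM in GFP cells with the largest rise in EtOH held 13.6% and 10.7% of the summed rise in the P300 Dex libraries, between the bounds of 5% and 25%. Of tested genes under 1 CPM in GFP cells of the other treatment, 73.1% and 27.3% had counts in P300 EtOH and 84.2% and 78.4% in P300 Dex. In the GFP libraries 89.0% to 93.2% had counts. Fewer genes with counts goes against an even spread, but the P300 libraries were also shallower.

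Genes were grouped by the first 3 letters of their symbols, which often do not stand for a gene family. Over 108 such groups of at least 20 tested genes, none passed among the 310 higher genes: the smallest adjusted one-sided Fisher's exact p was 0.202, for SLC symbols (13 of 319 higher) and CDH symbols (3 of 20), against 1.60% of all genes.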
